A study of Arabidopsis thaliana with 4 samples.

How the data were processed

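RNA was measured by paired-end sequencing (reads of 150 bases) of 10-day-old Arabidopsis thaliana seedlings grown on plates with 16 h of light and 8 h of darkness, per the labels. The 4 libraries were 2 of the wild type Col-0 and 2 of the mutant bdt1, described by the submitters as biological replicates. Groups and replicate numbers were taken from the sample titles. The titles and the genotype label read bdt1, while the source label of the mutant reads btl1; both were taken as names of 1 mutant. HISAT2 2.2.0, edgeR and the TAIR10 genome are named per the submitters' processing notes. The read counter, the gene annotation version and the strandedness of the counting are not given in the sources used here.

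The deposited table holds 32548 genes and gives for each library a normalised read count, a signal that is never negative and, apart from values of 0, mostly not a whole number. These deposited signal values had the form of counts adjusted by the authors to 1 common library size by matching quantiles of a negative binomial distribution, the form that edgeR gives to its pseudo-counts. This reading comes from the values: fitting relative library sizes and a dispersion of 0.00544 to the low values of each genotype, and inverting the adjustment, gave whole counts for 100% of values in each library, within a tolerance of 0.001 reads. The inversion was tested on simulated data, where it returned 100% of the counts for 8000 genes. Recovered totals were 23529796 and 27435729 reads in wild-type replicates 1 and 2, and 22914893 and 25120921 in bdt1 replicates 1 and 2. Because the deposited values are adjusted and not raw counts, the count test planned for raw counts gave way to the test planned for normalised values, and count tests were run on the recovered counts as alternatives. The edgeR quasi-likelihood test on the recovered counts called 303 genes higher and 214 lower.

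Genes with a mean normalised count of at least 1 were kept (23256 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(normalised count + 1) with a mean-variance trend and no block. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Fold changes are on the log2(normalised count + 1) scale, which understates the change of genes with low counts. For genes with 0 reads in wild type, the fold was computed against a floor of 3 reads over the group, with the bdt1 reads taken as observed. For genes with 1 to 3 reads there, a ratio with an exact binomial 95% interval was computed. The floor allows for counting error in wild type and not in bdt1, so folds against it are not full lower bounds. Floors and intervals cover no error beyond counting, since reads from amplified libraries are not independent molecules.

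Before the data were examined, 33 gene lists with 631 members were fixed from background knowledge. 1 member was left out because its symbol belongs to another gene in the reference table. Lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists, again with an estimated correlation, and with fry. All 32548 gene identifiers matched the TAIR10.1 annotation, which gave symbols, products and positions; the table itself carries no coordinates. Organelle-encoded genes were not analysed here.

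The genes named were set by a rule written before the data were examined. They are the 10 genes with the largest change in each direction among called genes with a mean of at least 2 and no overlap between genotypes, up to 4 called members of each list, and FLC, FT and SOC1. The gene the mutant is named for was to be added if the tables gave its symbol. Other genes are named as chosen after their values were seen.

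On simulated counts at the real means and library sizes, with 200 genes changed, limma run on 23210 genes for bdt1 against wild type recovered 44.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 87.9% of those changed 4-fold. Among genes with a mean of 100 or more the shares were 69.8%, 100% and 100%. Over all genes run, 6.29% of calls were false. The simulated genes varied independently, so a state shared by many genes of 1 library was not simulated. Alternatives were quantile normalisation, TMM scaling, other filters, other pseudocounts, limma without the trend, limma-voom, DESeq2 1.42.0 and edgeR 4.0.16 on the recovered counts, a replicate block, a 2-fold threshold, and each library left out in turn. The edgeR quasi-likelihood test was the main test planned for raw counts. Its use on the recovered counts, and the filter at a mean of 100, were decided after seeing the data. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served the other steps.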

Results

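Transcript levels were compared between wild-type Col-0 seedlings and bdt1 mutant seedlings, with 2 libraries of each genotype. The recovered totals ranged from 22914893 to 27435729 reads per library. Of 32548 genes, 23256 reached the mean normalised count of 1 needed for testing. The first principal component, with 49.2% of the variance, separated the genotypes. The second, with 27.4%, separated the 2 wild-type libraries.

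No gene carries the symbol BDT1 in the annotation used here. Background knowledge, and not the tables, ties the name to AT4G11560, which encodes a protein with a bromo-adjacent homology (BAH) domain, a module known to bind histones. AT4G11560 lies on chromosome 4 from 6999869 to 7003493 on the minus strand (TAIR10.1). Its normalised read count was 1135 and 1117 in the 2 wild-type libraries and 313 and 324 in the 2 bdt1 libraries. The transcript fell by 1.82 on the log2 scale (SE 0.08, limma adjusted p = 3.9e-05), or 3.53-fold, and was still present in bdt1.

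The comparison asked which transcripts differ between bdt1 and wild type. PORA, a light-dependent enzyme of chlorophyll synthesis, rose from 10.8 ± 1.71 to 794 ± 7.29 normalised reads (SD, n = 2 each), a log2 fold change of 6.09 (SE 0.19, limma adjusted p = 8.7e-06). AT3G44006, an uncharacterised gene, had 0 reads in wild type and 149 in bdt1, 52.7-fold higher against the floor of 3 reads. QQS, an orphan gene linked to starch content, fell from 116 ± 5.76 to 9.14 ± 0.473 (SD, n = 2 each), by 3.53 on the log2 scale. In all, 280 genes were higher and 199 lower in bdt1 (limma, adjusted p under 0.05), and 152 and 44 of them changed at least 2-fold. Higher genes had a median wild-type count of 148 and a median log2 fold change of 1.08. Lower genes had a median wild-type count of 1250 and a median log2 fold change of -0.60.

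Among the other large rises, AT2G41470, an agamous-like MADS-box gene, had 3 reads in wild type and 176 in bdt1, a ratio of 62.2 (95% interval 21 to 305). MEE65 had 2 and 73 reads, a ratio of 38.7 (10.3 to 326). AT2G21720 and AT5G33390 had 0 reads in wild type and were 15.2-fold and 12.7-fold higher against the floor of 3 reads. AT1G18830, a WD40 repeat gene, rose by 4.89 on the log2 scale, and AT1G75945 by 4.09. SBT3.3, a subtilisin-like protease, rose by 4.31, and the cupin gene AT5G39110 by 4.13. Among the falls, TEM2 and ACS7, which encodes an enzyme of ethylene synthesis, changed by -1.99 and -1.90. AT5G24240, a phosphatidylinositol 4-kinase-like gene, changed by -2.11, AT3G15450 by -1.96 and the kelch repeat gene AT1G80440 by -1.80. AT2G20670 was 4.01-fold lower. AT2G08735 changed by -2.68 and AT5G35480 by -1.85. Without wild-type replicate 2 the calls of ACS7 (-1.42), AT2G08735 (-2.64) and AT5G35480 (-2.12) were lost, as were those of AT2G08735 (-2.72) and AT5G35480 (-1.59) without wild-type replicate 1. The fitted fold moved by more than 1.5 times for SBT3.3 (19.8-fold; 9.45 without wild-type replicate 1 and 41.4 without replicate 2), AT5G39110 (17.5-fold; 9.92 and 30.9) and MEE65 (22.3-fold; 13.3 and 37.5).

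In all 479 called genes both bdt1 libraries lay on the same side of both wild-type libraries, a separation found in 48.9% of tested genes where chance gives 33.3%. Without bdt1 replicate 1 or replicate 2, limma called 0 genes, with 1573 and 1611 at an unadjusted p under 0.05, so every limma call named here was lost. The edgeR quasi-likelihood test on the recovered counts still called 145 higher and 78 lower genes without bdt1 replicate 1, and 165 and 135 without replicate 2. These kept 138 and 75, and 153 and 97, of the 280 and 199 main calls. Without wild-type replicate 1 limma called 540 higher and 776 lower genes. With limma's trend left out, 42 genes were higher and 6 lower, and 10 and 3 of the main calls were kept, among them from the genes named here PORA, AT3G44006, AT4G11560, QQS, AT1G75945 and ASY1. Other tests also ended calls of named genes. DESeq2 ended those of ARR7, AT2G08735, BIK1, CHE, DIN10, HAT2, HDG3, TEM1 and WAK1, and limma-voom those of ACS7, AT5G35480, DIN1, PR2, SUS4 and WRKY22. A pseudocount of 0.1 ended those of AGL38, AT2G08735, AT5G35480, BIK1, CRA1, DIN1, DIN10, HAT2, HDG3, KN, MEE65, PHE1, PR2, PRR5, SUS4 and WAK1. Quantile normalisation ended the call of BIK1, and other filters on low counts those of AGL38, HAT2, HDG3 and SUS4.

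**Figure D1:**
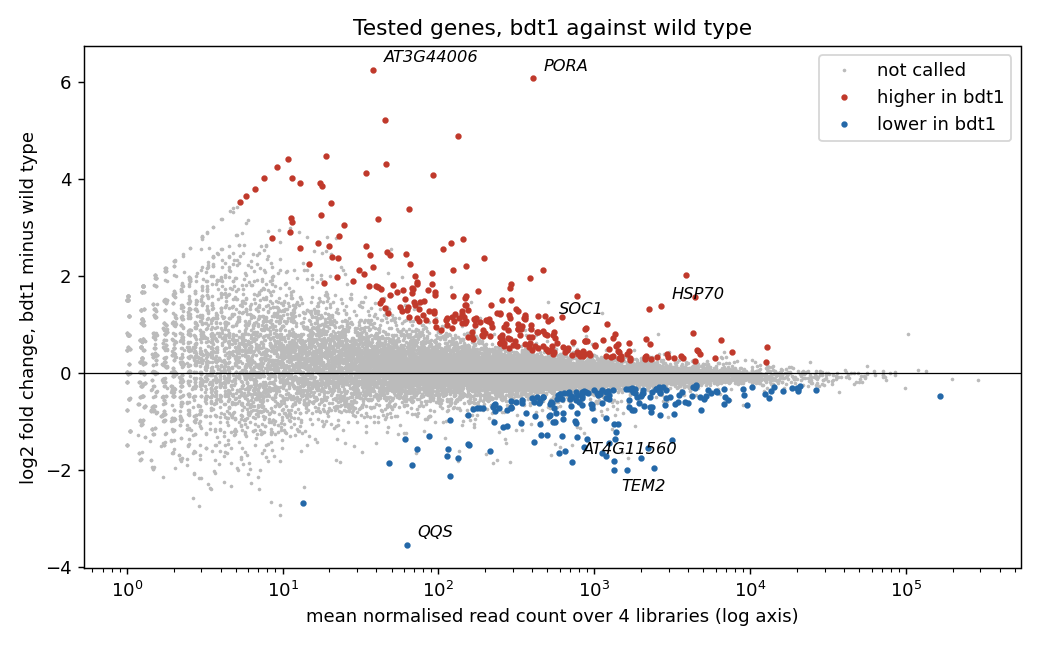
Log2 fold change of bdt1 minus wild type against the mean normalised read count over the 4 libraries (log axis) for the 23256 tested genes; coloured points are the 280 genes called higher and the 199 called lower by limma. Fitted fold changes of genes with 0 reads in wild type, such as AT3G44006, depend on the pseudocount.

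Flowering genes changed in both directions. SOC1, an integrator of flowering signals, rose from 325 ± 38.5 to 681 ± 28.7 (SD, n = 2 each), a log2 fold change of 1.07 (SE 0.10, limma adjusted p = 0.0028). FUL, a MADS-box promoter of flowering, rose by 1.66 (SE 0.22, adjusted p = 0.0095), and the floral MADS-box gene SEP4 by 1.17 (SE 0.12, adjusted p = 0.0032). TEM1 and TEM2, repressors of FT, both fell. The log2 fold change was -1.65 for TEM1 (SE 0.28, adjusted p = 0.025) and -1.99 for TEM2 (SE 0.21, adjusted p = 0.0034). TEM1 was at 1694 ± 633 in wild type and 538 ± 200 in bdt1, and TEM2 at 2156 ± 731 and 532 ± 108 (SD, n = 2 each). RAV1, a gene of the same family chosen after its values were seen, fell from 981 ± 382 to 311 ± 25.5 (SD, n = 2 each), by 1.60 on the log2 scale. FT itself, the mobile flowering signal, did not pass, at 76.5 ± 9.79 in wild type and 111 ± 7.86 in bdt1 (SD, n = 2 each; log2 fold change 0.54, SE 0.19, adjusted p = 0.22). The repressor FLC was at 23.2 ± 4.44 and 13.6 ± 5.72 and did not pass (log2 fold change -0.77, SE 0.42, adjusted p = 0.41). The call of TEM1 was lost without wild-type replicate 2 (-1.26).

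Of 15 tested floral promoters and integrators, 2 rose, 0 fell and 12 had a positive log2 fold change, with 2 higher when adjusted over the list alone. The list was shifted up against other genes (camera adjusted p = 5.2e-04, and adjusted p = 0.54 with an estimated correlation). Of 14 floral repressors, TEM1 and TEM2 fell, and 1 was higher and 2 lower when adjusted over the list alone. That list was shifted down (camera adjusted p = 0.009, and adjusted p = 0.54 with an estimated correlation). SEP4 was the 1 called member of 10 floral organ identity genes, also when adjusted over the list alone. 9 of the 10 had a positive log2 fold change (camera adjusted p = 0.013, and adjusted p = 0.54 with an estimated correlation). None of 28 regulators of FLC passed, also when adjusted over the list alone.

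**Figure D2:**
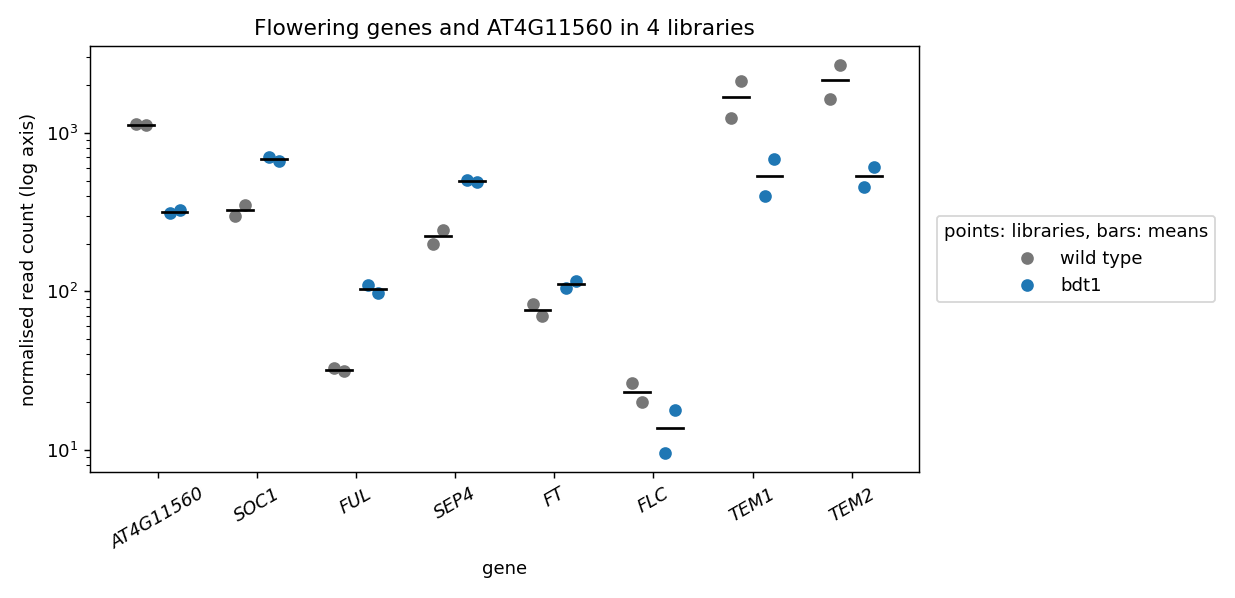
Normalised read counts (log axis) of AT4G11560 and 7 flowering genes in each of the 4 libraries; points are libraries and bars are the means of 2. SOC1, FUL and SEP4 were higher and TEM1, TEM2 and AT4G11560 lower in bdt1, whereas FT and FLC did not pass the test.

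Of 20 tested iron deficiency genes, 7 rose and 0 fell, 9 were higher when adjusted over the list alone, and 5 had a negative log2 fold change. BHLH38 and BHLH39, transcription factors induced by low iron, rose 2.85-fold (log2 SE 0.21) and 2.3-fold (log2 SE 0.16). IMA2, which encodes an iron-responsive peptide, rose by 1.14 (SE 0.11) on the log2 scale and the ferric reductase gene FRO3 by 0.81 (SE 0.10). The iron uptake genes IRT1 and FRO2 and their regulator FIT, chosen after their values were seen, did not pass, at log2 fold changes of -0.89 (SE 0.37), -0.38 (SE 0.24) and 0.09 (SE 0.16). IRT1 was at -0.31 without bdt1 replicate 1 and -1.48 without bdt1 replicate 2, and FIT at -0.12 without wild-type replicate 1. The list was shifted up (camera adjusted p = 1.6e-05, and adjusted p = 0.54 with an estimated correlation). Of 20 heat shock genes, 3 rose and 0 fell, and 4 were higher and 1 lower when adjusted over the list alone. The chaperone genes HSP70 and HSP90.1 rose by 1.39 (SE 0.07) and 0.66 (SE 0.07), and the stress regulator DREB2A by 1.13 (SE 0.16). The list was shifted up (camera adjusted p = 0.02, and adjusted p = 0.54 with an estimated correlation).

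Of 21 salicylic acid defence genes, PR2, a glucanase, and the kinase WAK1 rose by 2.22 (SE 0.40) and 1.02 (SE 0.18), and 3 were higher when adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.54 with an estimated correlation). CRA1, a seed storage protein gene, rose by 1.59 (SE 0.30) among 17 seed maturation genes, of which 15 had a positive log2 fold change and 4 were higher when adjusted over the list alone (camera adjusted p = 3.3e-04, and adjusted p = 0.54 with an estimated correlation). The response regulator ARR7 rose by 0.57 (SE 0.11) among 14 cytokinin response genes, of which 4 were higher when adjusted over the list alone (camera adjusted p = 0.0061, and adjusted p = 0.54 with an estimated correlation). None of 17 root hair genes passed, also when adjusted over the list alone, while 15 had a positive log2 fold change (camera adjusted p = 0.029, and adjusted p = 0.54 with an estimated correlation). Without wild-type replicate 2 the calls of PR2 (log2 fold change 2.37) and CRA1 (2.14-fold higher) were lost. PR2 was 4.67-fold higher, 7.78-fold without bdt1 replicate 1 and 2.81-fold without bdt1 replicate 2.

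Of 20 light-harvesting and Rubisco small subunit genes, 9 fell and 0 rose, and 13 were lower and 1 higher when adjusted over the list alone. LHCB3 fell by 0.65 (SE 0.07), LHCB2.1 by 0.60 (SE 0.07), LHCB2.2 by 0.49 (SE 0.06) and LHCB4.2 by 0.42 (SE 0.06). All 9 encode chlorophyll-binding antenna proteins, and none of the 4 Rubisco genes passed. The list was shifted down (camera adjusted p = 5.1e-08, and adjusted p = 0.54 with an estimated correlation). Reads of near-identical copies such as LHCB2.1 and LHCB2.2 could have been split between them, so their single values are uncertain.

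Of 25 jasmonate genes, 3 fell and 1 rose, and 9 were lower and 1 higher when adjusted over the list alone. AOS and AOC1, enzymes of jasmonate synthesis, fell by 0.83 (SE 0.10) and 0.82 (SE 0.11), and the repressor gene JAZ2 by 0.47 (SE 0.08), while the lipoxygenase gene LOX3 rose by 0.86 (SE 0.11). The list was shifted down (camera adjusted p = 0.0016, and adjusted p = 0.56 with an estimated correlation). WRKY22, a transcription factor, and BIK1, a receptor-associated kinase, fell by 1.74 and 0.41 among 19 genes of pattern-triggered immunity, also when adjusted over the list alone, where 2 were lower (camera adjusted p = 6.4e-04, and adjusted p = 0.58 with an estimated correlation). DIN1 and DIN10, induced in darkness, fell 2.14-fold and 1.69-fold among 17 sugar starvation genes, where 2 were lower when adjusted over the list alone (camera adjusted p = 0.02, and adjusted p = 0.68 with an estimated correlation). Without wild-type replicate 2 the calls of JAZ2 (-0.40), WRKY22 (-1.31), BIK1 (-0.35), DIN1 (-0.77) and DIN10 (-0.55) were lost.

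The cytokinesis gene KN fell by 0.42 among 27 cell division genes, of which 25 had a negative log2 fold change and 7 were lower when adjusted over the list alone (camera adjusted p = 8.1e-06, and adjusted p = 0.54 with an estimated correlation). CYP79B3 fell by 0.50 among 23 glucosinolate genes, of which 2 were lower when adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.54 with an estimated correlation). No member passed over all genes in 4 further lists that were shifted down. These were phosphate starvation (camera adjusted p = 6.5e-05), nitrate response (1.3e-04), stomatal lineage (1.9e-04) and flavonoid genes (0.0018). With an estimated correlation the adjusted p = 0.54 held for the first 3 and adjusted p = 0.58 for flavonoid genes. When adjusted over the list alone, 4 phosphate, 6 nitrate, 5 stomatal and 0 flavonoid genes were lower. The call of KN was lost without wild-type replicate 2 (-0.46).

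The other 14 lists were not shifted. Among them KIN1 rose by 1.14 while COR15A and COR413IM1 fell by 0.93 and 0.59, all 3 from the list of 32 abscisic acid, dehydration and cold genes, where 3 were higher and 2 lower when adjusted over the list alone. XTH17, a cell wall enzyme, rose by 0.90 among 21 expansin and xyloglucan genes, where 4 were higher and 2 lower when adjusted over the list alone. PRR5 and CHE fell by 0.60 and 0.43 among 23 clock genes, where 1 was higher and 3 lower when adjusted over the list alone. SUS4 rose by 0.42 and LBD41 fell by 0.71 among 15 hypoxia genes, where 2 were higher and 2 lower when adjusted over the list alone. HAT2 fell by 0.48 among 11 shade avoidance genes, where 1 was lower when adjusted over the list alone. Without wild-type replicate 2 the calls of PRR5 (-0.47), CHE (-0.41), SUS4 (0.43), LBD41 (-0.76) and HAT2 (-0.52) were lost, as was that of HAT2 without wild-type replicate 1 (-0.43). No member of the fixed ethylene, auxin, gibberellin and brassinosteroid, DNA damage, oxidative stress, root endodermis, shoot meristem or reference lists passed over all genes (ACS7, which fell, is not on the ethylene list). Of these, 1 ethylene gene was higher, and 2 ethylene genes and 1 oxidative stress gene lower, when adjusted over the list alone.

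Across the 33 lists, camera with the preset correlation called 19, 8 up and 11 down, and 11 without wild-type replicate 2. Called lists also held members whose log2 fold change had the opposite sign to the shift, of which LOX3 alone passed. In lists shifted up and not tallied above, 8 of 20 heat shock, 5 of 21 salicylic acid defence and 2 of 14 cytokinin genes had a negative sign. In lists shifted down a positive sign was found in 5 of 14 floral repressors, 5 of 20 light-harvesting and Rubisco, 9 of 25 jasmonate, 4 of 19 pattern-triggered immunity, 5 of 17 sugar starvation, 3 of 23 glucosinolate, 3 of 21 phosphate starvation, 3 of 17 nitrate, 1 of 14 stomatal and 5 of 20 flavonoid genes. Without wild-type replicate 2 the calls of floral repressors (adjusted p = 0.12), floral organ identity (0.13), pattern-triggered immunity (0.14), jasmonate (0.21), heat shock (0.1), flavonoid (0.21), sugar starvation (0.86) and root hair genes (0.14) were lost. Without wild-type replicate 1 those of salicylic acid defence (0.13) and root hair genes (0.055) were lost, and without bdt1 replicate 1 those of floral repressors (0.067), heat shock (0.079), flavonoid (0.13) and sugar starvation genes (0.1). Quantile normalisation ended the calls of floral organ identity (0.081), heat shock (0.078) and root hair genes (0.17), and limma without the trend those of heat shock (0.077) and sugar starvation genes (0.077). On edgeR fits the call of glucosinolate genes was also lost without wild-type replicate 1 (0.064). Some settings added calls, all down. These were abscisic acid, dehydration and cold (0.015), oxidative stress (0.0068) and ethylene genes (0.038) without wild-type replicate 1, and auxin genes (0.017) with a filter at a mean of 100. On edgeR fits the same 3 lists were added without wild-type replicate 1 (0.012, 1.6e-04 and 0.018), DNA damage genes without wild-type replicate 2 (0.043) and oxidative stress genes without bdt1 replicate 2 (0.019). With an estimated correlation camera called 0, with 1 at an unadjusted p under 0.05. The fry test asks another question, whether a list differs from no change, and called 1 list in one direction (root hair genes) and 21 in either direction. The median or mean and the camera direction differed in sign in the auxin, shade avoidance, shoot meristem and abscisic acid lists, none of which was shifted. Genes that overlap another gene could hold its reads, since the strandedness of the counting is not given in the sources used here. This holds for MEE65, SBT3.3, ASY1, BGLU19, WAK2, AT5G24240, AT3G15450, BHLH38, FRO3, LHCB3, LHCB4.2, DREB2A, DIN10, KN and FLC.

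**Figure D3:**
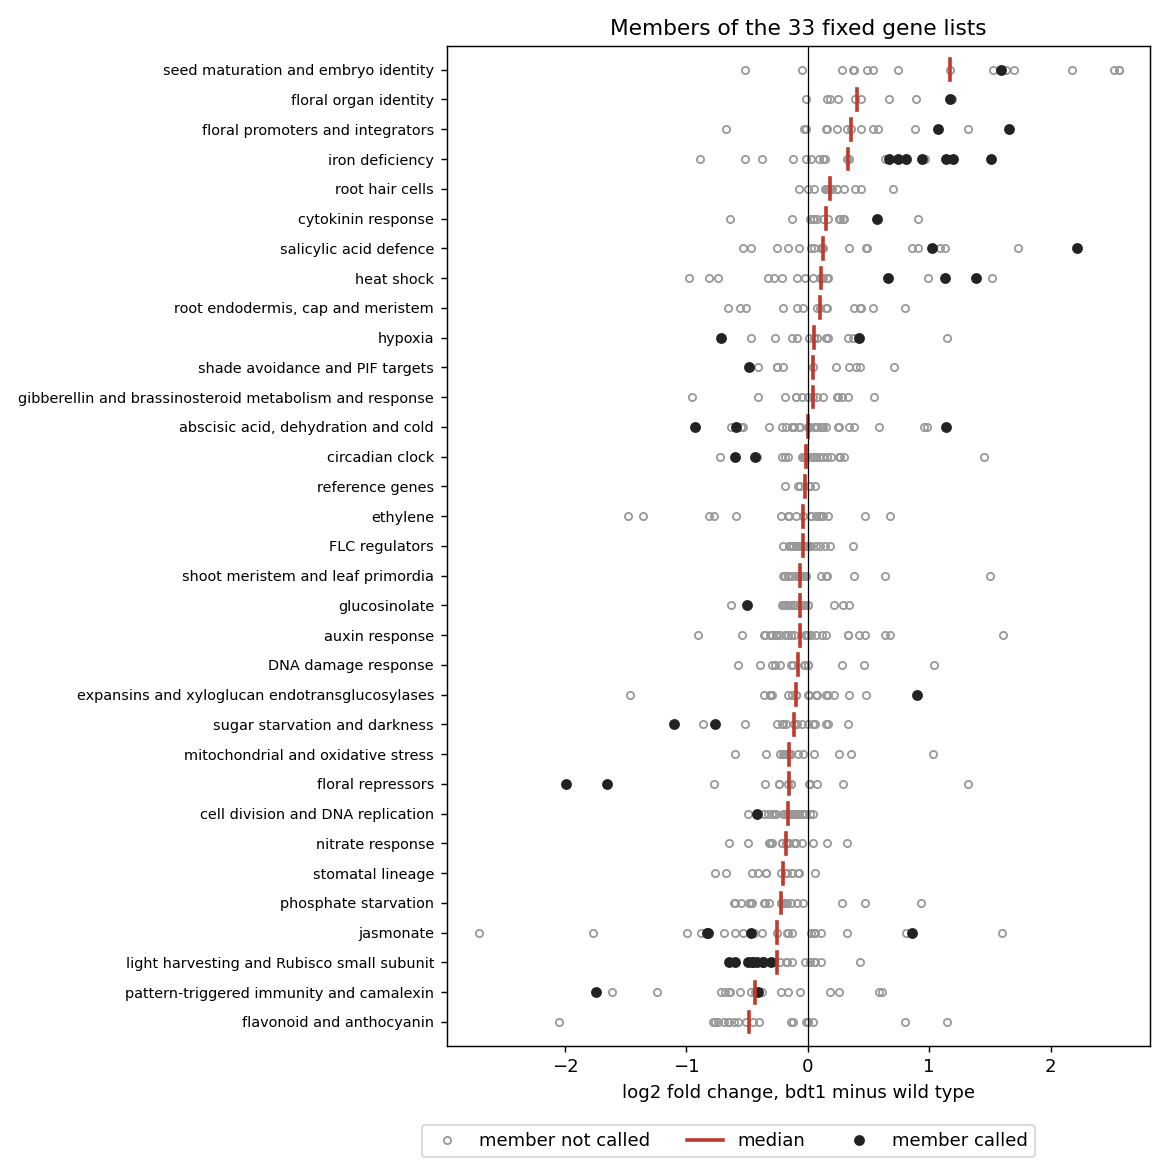
Log2 fold change of bdt1 minus wild type for each tested member of the 33 fixed gene lists, ordered by list median (red bar); filled points are members called by limma. In the iron deficiency list 7 members were called higher, and in the light-harvesting list 9 were called lower.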

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

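No called gene of the 479 changed sign under any alternative that tested it, and the median log2 fold change over all genes stayed between -0.016 and 0.007. In all 479, both bdt1 libraries lay on the same side of both wild-type libraries. Leaving out a library, or changing limma's filter, trend, pseudocount or block, could therefore not turn a sign, so the signs kept there test nothing. The counts of 280 higher and 199 lower genes depended on the fit and on the libraries kept. limma without its trend gave 42 and 6, a replicate block 901 and 917 (with the root hair list no longer called, adjusted p = 0.051), and a pseudocount of 0.1 gave 194 and 123. A 2-fold threshold gave 152 and 44 by leaving genes out, and a filter at a mean of 100 gave 182 and 172. That filter left 94 of the main calls untested, while other calls, such as that of SUS4, were tested and lost. What moved the counts beyond leaving genes out was not tested. With each library left out, limma gave 0 to 540 higher genes, 0 to 776 lower genes and 11 to 20 shifted lists. edgeR, chosen after seeing the data like the filter at a mean of 100, gave 781 and 1144 without wild-type replicate 1 and 1021 and 1030 without wild-type replicate 2. Leaving out 1 library leaves a lone sample assumed to vary like the other genotype, and the limma calls of 0 came from leaving out either bdt1 library, where edgeR called 145 and 78 (without replicate 1) or 165 and 135 (without replicate 2). Shifted lists fell from 19 to 0 with an estimated correlation. fry, which tests a list against no change and not against other genes, called 1 in one direction and 21 in either. CBSX6, not called, changed sign without wild-type replicate 1 (-0.11, and -0.10 with edgeR), against 0.23 without wild-type replicate 2. FIT, not called, did so too (-0.12, and -0.11 with edgeR), against 0.29 without wild-type replicate 2, and of the alternatives run IRT1 passed only with the replicate block (adjusted p = 0.024). The replicate numbers are shared between genotypes. The replicate differences of the genotypes correlated at -0.012 across genes, so no pairing showed over all genes together. A pairing that acts on some genes is not excluded by that value, so whether the numbers pair the libraries stays unknown. Low counts limited depth: 26 higher genes had a wild-type mean under 5.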

Other observations

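Tests of seed and flower tissue, of the wild-type replicates and of chance neighbours, with the recount that leaves out similar copies, were chosen after the result was seen, as were the intervals of the clock and Rubisco tests and the use of the Rubisco median to decide. The genes first named in this part were chosen after their values were seen. ASY1, a protein of the meiotic chromosome axis, rose from 36.2 ± 4.74 to 252 ± 2.03 normalised reads (SD, n = 2 each), a log2 fold change of 2.77 (limma adjusted p = 4.3e-04). The MADS-box gene PHE1 had 2 reads in wild type and 49 in bdt1, a ratio of 26 (95% interval 6.82 to 221), and its fitted 15.2-fold rise was 9.0-fold without wild-type replicate 1 and 25.5-fold without replicate 2. AGL38, a MADS-box gene, and HDG3, a homeobox gene, had 0 reads in wild type and were 9.2-fold and 8.13-fold higher against the floor of 3 reads. Both calls were lost without wild-type replicate 2 (3.79 and 3.65 on the log2 scale). On chromosome 1 (TAIR10.1) AGL38 (24254929 to 24255857), XTH17 (24257054 to 24258506) and PHE1 (24266257 to 24267336) were higher. CBSX6 (24259880 to 24262998), between XTH17 and PHE1, did not pass (log2 fold change 0.06, limma adjusted p = 0.82, and -0.11 without wild-type replicate 1). Reads shared between AGL38 and PHE1 were not checked, since only adjacent tested genes were compared for shared sequence.

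The 26 higher genes with a wild-type mean under 5 rose by a median of 22.9 normalised reads (10.6 to 87.8). The median rise of 11 seed storage and oleosin genes was 0.22 of that (bootstrap 95% interval 0.02 to 0.69). Seed or silique tissue in the bdt1 libraries stays open all the same, since no table gives the ratio it would bring, the 26 genes were picked for rising, and CRA1 among the 11 rose by 121, more than any of the 26. For 6 floral organ genes the ratio was 0.30 (0.01 to 1.76), an interval too wide to exclude flower tissue. No biological explanation was tested, and the genotype stays open as one.

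For the genes lower in bdt1, a harvest at another time of day was predicted beforehand to part evening from morning clock genes. Their medians were to lie on opposite sides of 0 and differ by at least 0.5. The medians were 0.04 for evening and 0.23 for morning genes. They differed by -0.18 (interval from the standard errors -0.39 to 0.03), although PRR5 and CHE fell. The morning genes were at 0.19 (CCA1), 0.27 (LHY), 0.07 (RVE8) and 1.45 (PRR9, limma adjusted p = 0.45), and the evening genes at -0.04 to 0.30. The medians lay under that cut, but a smaller shift in time would part the genes by less and is not excluded. A smaller share of green tissue would lower the 4 Rubisco genes with the light-harvesting genes. Their median change was 0.00 of the median light-harvesting fall (-0.19 to 0.27), below 0.5. The rule set beforehand against this explanation used the largest fall among the 4 instead. That was 0.39 of the median light-harvesting fall, under the 0.5 set beforehand, so the rule as written counts against this explanation. Its interval (0.06 to 0.92), added after the result was seen, reaches past 0.5, so the largest fall leaves doubt. A state that also varies between the 2 wild-type libraries stays open: 60.3% of the lower genes were higher in wild-type replicate 2 than in replicate 1, above the central 95% of 10000 draws matched on expression (45.2% to 58.8%) and inside their full range. The higher genes also leaned toward replicate 2 (56.8%, matched draws 43.9% to 55.4%), whereas a single state covering both sets would turn them opposite ways. AT1G80440, one of the lower genes, was at 2112 ± 1015 in wild type (SD, n = 2). Wild-type replicates 1 and 2 were at 1394 and 2829 for AT1G80440, 1247 and 2142 for TEM1, and 1639 and 2673 for TEM2. Likewise they were at 711 and 1251 for RAV1, 73.5 and 144 for ACS7, and 147 and 266 for WRKY22. Other lower genes were not higher in replicate 2, such as AT5G24240 (214 and 172) and AT5G35480 (89.6 and 62). AT4G11560, the gene tied above to the name bdt1, was at 1135 and 1117.

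The 280 higher genes formed 12 pairs of adjacent tested genes, against 3.36 in 10000 random draws (p = 0.0002, one-sided permutation test), among them RLK1 with FUL, and BGLU19 and BGLU24 each with a mannose-binding lectin gene. The 199 lower genes formed 6 pairs against 1.68 (p = 0.0053, one-sided permutation test), so the excess was not limited to higher genes. Shared reads between tandem copies stay open: a share of 0.67 of the pairs had different products, past the 0.5 set beforehand against that explanation, but product names proved a poor guide, since WAK1 and WAK2 differ in name and share 4.39% of 50-base windows. Without pairs that share such a window 7 remained, against 3.05 in draws counted the same way (p = 0.036, one-sided permutation test), no more than the 7 that bound the central 95% of draws. This recount is not a clean test of copies. It dropped MEE65 with RPI2, which overlap, and kept BHLH38 with BHLH39, which have the same product. Neighbouring genes may rise together, and this recount leaves that undecided.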
